A study of Mus musculus with 6 samples.

How the data were processed

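RNA was measured in cultured aortic smooth muscle cells of C57BL/6 mice that stably carried either a control lentivirus or a lentivirus for the microRNA miR-30e. There were 3 control arrays and 3 miR-30e arrays. Per the labels' protocols, total RNA was extracted with a kit that also retains small RNA, copied with an oligo-dT primer carrying a T7 promoter, and transcribed into biotin-labelled cRNA for Affymetrix arrays. The sibling experiments of the study on mesenchymal stem cells were not analysed here. The labels do not say that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

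The authors deposited 1 table of log2-scale values with 28815 probe sets and 6 array columns. The array software, background correction and normalization used by the authors were not given in the sources used here. Each probe set had been centred on its median over the 6 arrays, since the largest absolute row median was 5e-07. The medians of the 6 arrays lay between -0.013 and 0.016, and no further normalization was applied, because the rule set in advance called for it only at a spread above 0.1. The base of the logarithm was not stated and was taken as 2. The largest range within a probe set was 7.54, which a base of 10 could not give for a scanner image, but a natural logarithm was not excluded; in that case every fold given here would be too small. Higher values were taken as more RNA. Because of the centring, expression levels, detection and signal over background are unknown here, and no gene's level can be set against another's. Depth has no meaning for these arrays, and their number limits the precision.

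Gene names came from the platform's probe annotation, updated through Entrez identifiers to the RefSeq gene table of assembly GRCm38.p6. Of the probe sets, 21780 had 1 gene symbol, 1605 had several and 5430 were not listed; 21689 of the first kind matched an identifier. Only probe sets with 1 symbol were named. The values of a gene's probe sets were averaged, which gave 19935 genes. Of these, 18937 had 1 probe set and 998 had several, and 0 genes had probe sets that passed the threshold in opposite directions. The design fixed before the data were examined had called for a filter on dim genes and for the brightest probe set of each gene. Neither can be applied to centred values, so all genes were kept and the mean of the probe sets was used in place of the brightest.

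Differences are miR-30e minus control on the log2 scale, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 6 arrays, group as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors after a difference are standard errors from this fit, with n = 3 arrays per group. The 25 gene lists were fixed before the data were examined and were tested with limma's camera, which compares the genes of a list with all other genes, at a preset inter-gene correlation of 0.01. Camera with a correlation estimated for each list and fry, which asks whether a list moves in a single direction on balance, were run beside it. With an estimated correlation, camera also takes its degrees of freedom from the 6 arrays rather than from the genes, which raises its p-values. Camera and fry p-values were adjusted over the 25 lists; those of 6 further lists, made after seeing the data, were adjusted over these 6 alone. Single genes were also adjusted over each list alone. The planned test of genes with miR-30 seed matches in their 3' untranslated regions was not run, since transcript sequences were not used here.

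Named genes followed a rule fixed in advance. It took 12 primary genes, the 10 largest rises and 10 largest falls among genes past the threshold whose miR-30e arrays all lay beyond the control arrays, and up to 4 members with the smallest p of each list. Of the primary genes, 2, Runx2 and Spp1, had no probe set with a single named gene and were not analysed here. Genes named outside the rule are the Mir30e probe set and, in the closing section, members of the lists made after seeing the data and further members of fixed lists, chosen after their values were seen.

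The gene test and camera were tested on simulated data of the same 19935 genes with the measured spread of each gene. The gene test recovered 58% of 100 genes simulated with a log2 change of 0.5, 90% of 50 at 1 and 100% of 50 at 2, with 4 false calls among 157. Far more genes, 4282, were called in the data, so these shares do not carry over directly. Camera called the shifted list and 0 of the null lists, but the simulated genes were independent of each other, which real genes are not. Alternatives run were quantile normalization, median centring of arrays, every probe set tested singly, a 2-fold threshold, a replicate block, each array left out in turn and the other set tests. Added after seeing the data were a robust variance model, protein-coding genes only, genes with 1 probe set only, quantile normalization of gene means, a small nucleolar RNA covariate, leaving out 2 miR-30e arrays together, and the miR-30 target and IGF axis lists without Igf2. Filters on dim probe sets, the pseudocount and the intensity trend could not be applied to centred values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.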

Results

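The series profiled mouse aortic smooth muscle cells, the contractile cells of the vessel wall, that stably expressed miR-30e or a control lentivirus. miR-30e is a small RNA that lowers the output of messenger RNAs bearing matching sites. The study asked what this microRNA does in smooth muscle and mesenchymal stem cells, with an interest in Igf2 and bone formation. Each group held 3 arrays, and values were deposited on a log scale, centred per probe set. Across genes, the centred values of arrays correlated at 0.61 to 0.77 within the control group, 0.52 to 0.70 within the miR-30e group and -0.76 to -0.59 between groups; the centring itself contributes to the negative sign. The first principal component held 76.1% of the variance and separated the groups.

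In miR-30e cells, Saa3, an acute-phase serum amyloid gene, fell by 7.36 ± 0.10 on the log2 scale (SE, n = 3 per group), a 165-fold difference, or 83.0-fold after quantile normalization of the arrays. Igf2, the growth factor insulin-like growth factor 2, fell by 3.91 ± 0.15, or 15.1-fold (limma adjusted p = 6.50e-07), and by 3.27 after quantile normalization of gene means, an alternative chosen after seeing the data. Among the largest rises were Ctsk, the collagen-degrading protease cathepsin K, at 3.17 ± 0.11, and the smooth muscle genes Actg2 (3.16 ± 0.24) and Tagln (2.31 ± 0.18). After quantile normalization Ctsk differed by 3.85 and Actg2 by 3.82. This step gives all arrays a common set of values, and in these centred data the largest falls exceeded the largest rises. Here it enlarged the 10 largest rises and shrank the 10 largest falls, while smaller falls went both ways.

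In all, 4282 of 19935 genes (21.5%) changed, 1918 higher and 2364 lower in miR-30e cells. A change of at least 2-fold was found in 442 genes, 161 higher and 281 lower, and of at least 4-fold in 22 higher and 56 lower. The miR-30e arrays all lay beyond the control arrays in 34.7% of genes, where chance gives 10%. The median difference over all genes was 0.0052. With the small nucleolar RNA median of each array as a covariate, an alternative chosen after seeing the data, 2539 genes changed. This covariate was mostly higher in the controls, so it takes up part of the group difference.

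The other large falls were Sfrp1, a secreted Wnt antagonist (-5.24 ± 0.18), the neutrophil-attracting chemokine Cxcl5 (-4.96 ± 0.48, and -5.68 without miR-30e replicate 1), haptoglobin, Hp (-4.77 ± 0.13), the chemokine Cxcl15 (-4.58 ± 0.27), the BMP antagonist Grem1 (-4.25 ± 0.10), the cholesterol 25-hydroxylase Ch25h (-4.18 ± 0.12), lipocalin 2, Lcn2 (-3.80 ± 0.39), and the chitinase-like gene Chil1 (-3.62 ± 0.09). The other large rises were Perp, a p53 target (3.12 ± 0.12), the potassium channel Kcnt2 (2.50 ± 0.10), the mitochondrial folate enzyme Aldh1l2 (2.48 ± 0.14), the fibrillar collagen Col3a1 (2.38 ± 0.13), the keratin Krt19 (2.32 ± 0.13, and 2.92 after quantile normalization), the adhesion receptor Adgrg6 (2.31 ± 0.09) and the serine protease Htra1 (2.29 ± 0.10). Adjusted p-values of these 20 genes, Saa3, Igf2, Ctsk, Actg2 and Tagln among them, lay between 5.16e-10 and 0.000149. Quantile normalization of gene means moved the fold of all 20 by over 1.5 times, the rises to 2.92 to 4.56 and the falls to -5.48 to -3.01. These shifts had the same directions as those from quantile normalization of the arrays.

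**Figure D1:**
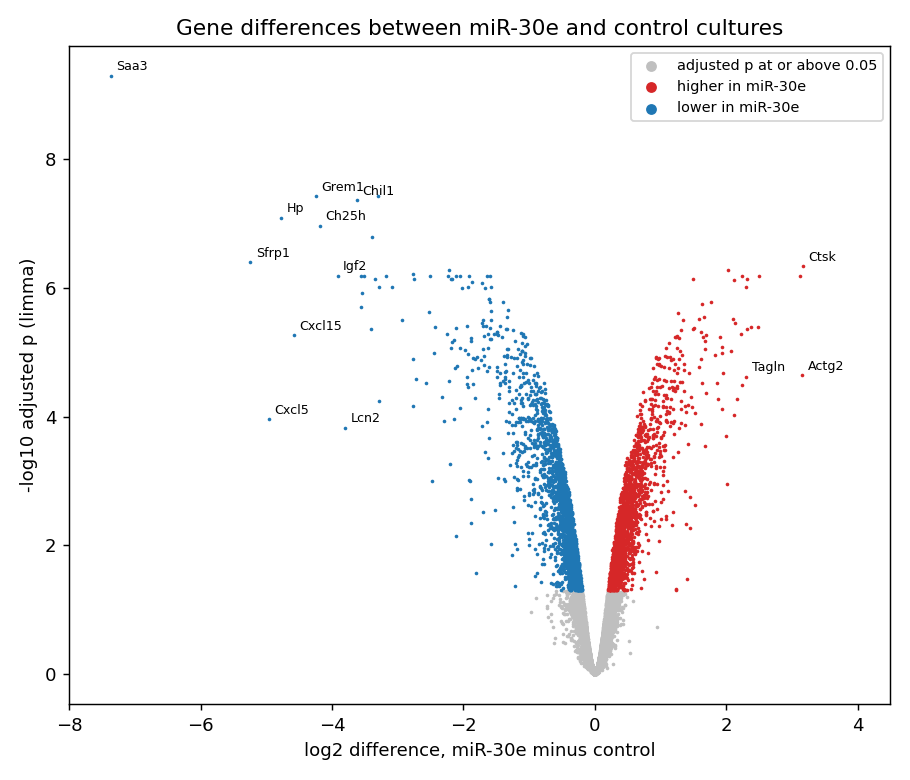
Log2 difference (miR-30e minus control, x axis) against -log10 of the limma adjusted p (y axis) for each of 19935 genes, with the 10 largest falls and 3 of the 10 largest rises labelled. Of the genes, 1918 were higher (red), 2364 were lower (blue) and the rest did not pass the threshold (grey).

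**Figure D2:**
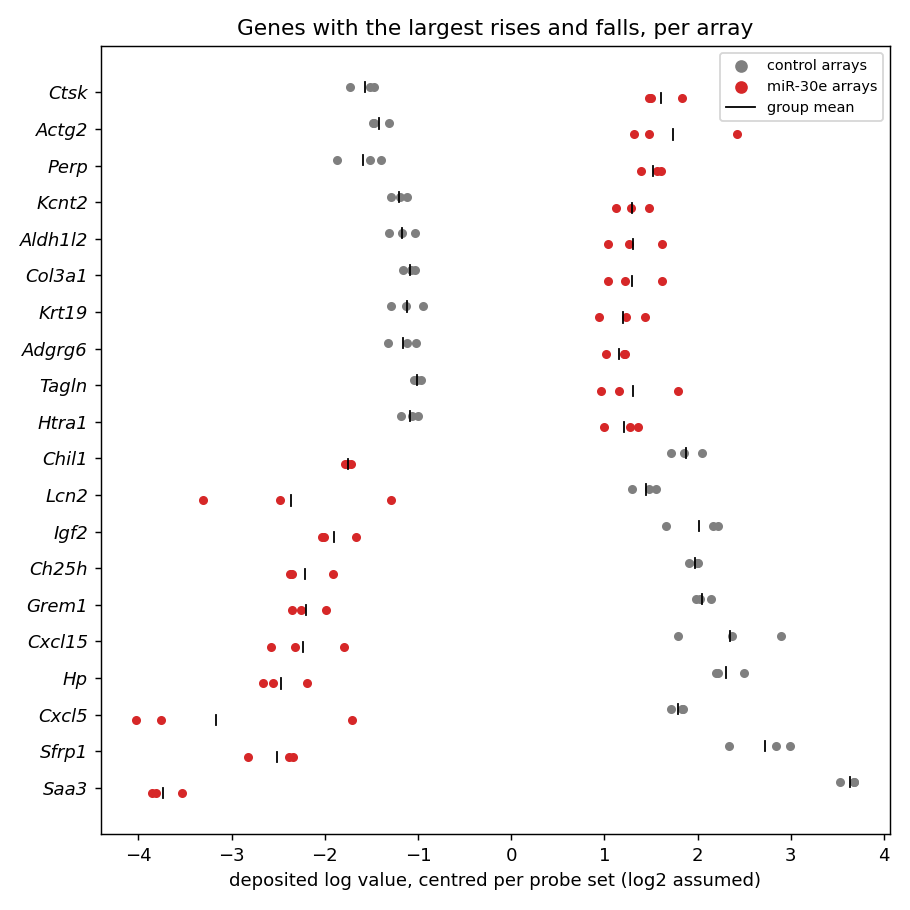
Deposited log values, centred per probe set (x axis, log2 assumed), of the 10 genes with the largest rise and the 10 with the largest fall, with a point per array (3 control, 3 miR-30e) and a bar at each group mean. The control and miR-30e arrays do not overlap for these genes, which the rule for naming them required; Cxcl5 and Lcn2 had the widest spread among the miR-30e arrays of the falling genes.

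Contractile smooth muscle genes rose in miR-30e cells. Of 29 measured members, 15 rose, 1 fell and 13 did not pass; adjusted over the list alone, 16 rose and 1 fell. Actg2, the enteric smooth muscle actin, rose with Tagln (transgelin), the actin-binding calponin Cnn1 (2.16 ± 0.19) and the LIM-domain gene Fhl1 (2.08 ± 0.13). Acta2, the smooth muscle actin most used as a marker, rose by 0.46 ± 0.12 (adjusted p = 0.0209), and lost its call when any of the 3 control arrays was left out (adjusted p = 0.0528 to 0.0812), or with the small nucleolar RNA covariate (adjusted p = 0.125). Myh11, the smooth muscle myosin heavy chain and a marker of mature cells, differed by 0.11 ± 0.07 and did not pass (adjusted p = 0.348). The list had a camera adjusted p of 2.85e-07 at the preset correlation, and adjusted p = 0.468 with an estimated correlation.

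Inflammatory mediators fell: 0 of 34 measured members rose, 20 fell and 14 did not pass, and adjusted over the list alone 21 fell. Beside Saa3 these included the alarmin Il33 (-3.56 ± 0.17), the inducible nitric oxide synthase Nos2 (-1.49 ± 0.09) and the toll-like receptor Tlr2 (-1.05 ± 0.08). The median difference of the list was -0.73 and its camera adjusted p was 1.52e-10, with adjusted p = 0.468 with an estimated correlation. Among macrophage and leukocyte markers, 0 of 25 rose and 2 fell, Cd14 (-1.10 ± 0.11) and Cd68 (-0.76 ± 0.07), also adjusted over the list alone, and the list median was 0.061. The pan-leukocyte gene Ptprc (0.23 ± 0.09) and the leukocyte tetraspanin Cd53 (0.22 ± 0.07) did not pass; Ptprc did without miR-30e replicate 1 (adjusted p = 0.0242), and Cd53 after quantile normalization of gene means (adjusted p = 0.0417). The interferon response list had 5 higher and 3 lower of 36 (6 and 3 adjusted over the list alone), with Ifi27 at 0.99 ± 0.08 and Ifit2 at -0.83 ± 0.10, and did not pass camera (adjusted p = 0.940).

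Genes of the insulin-like growth factor axis were lower on balance, with 2 of 20 higher and 9 lower (2 and 11 adjusted over the list alone). Next to Igf2, the glycoprotein Stc1, which restrains the protease that frees IGF, fell by 2.14 ± 0.13, and the binding protein Igfbp5 fell by 1.37 ± 0.10. Htra1, a protease that can cleave IGF-binding proteins, rose. The camera adjusted p was 0.00582, and adjusted p = 0.468 with an estimated correlation. Igf2, the gene the study took up, is not independent evidence here either; without it the list mean went from -0.54 to -0.37 and the camera adjusted p to 0.0334.

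In TGF-beta and BMP signalling, 12 of 31 genes fell and 4 rose (15 and 5 adjusted over the list alone). With Grem1, the co-receptor Tgfbr3 fell by 1.58 ± 0.08, the matrix protein Tgfbi by 1.64 ± 0.12 and the BMP-responsive regulator Id4 by 1.45 ± 0.13. The camera adjusted p was 0.00354, and adjusted p = 0.468 with an estimated correlation. Of 28 Wnt genes, 10 fell and 3 rose, both over all genes and adjusted over the list alone. They included Sfrp1, the Wnt inhibitor Nkd2 (-1.93 ± 0.08), the receptor Fzd4 (-1.39 ± 0.07) and the co-receptor Lrp5 (-0.81 ± 0.07). Camera did not call the list (adjusted p = 0.0523), but did without control replicate 1 (adjusted p = 0.0402) or miR-30e replicate 2 (adjusted p = 0.0169), and fry called it lower (adjusted p = 0.00826). In Notch signalling 3 rose and 4 fell of 18, also over the list alone, with the ligand Jag1 at 1.27 ± 0.15 and the smooth muscle receptor Notch3 at -0.52 ± 0.09 (camera adjusted p = 0.808).

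Glycolytic and hypoxia-responsive genes fell, with 18 of 27 lower and 3 higher (19 and 4 adjusted over the list alone). Hexokinase 2, Hk2, fell by 1.31 ± 0.11, the mitophagy gene Bnip3 by 1.24 ± 0.13, the pyruvate dehydrogenase kinase Pdk1 by 1.20 ± 0.13 and the phosphoglycerate mutase Pgam1 by 0.83 ± 0.09. The camera adjusted p was 9.56e-07, and adjusted p = 0.503 with an estimated correlation. Cholesterol synthesis genes also fell, 11 of 20 with 0 higher (14 adjusted over the list alone), led by the squalene epoxidase Sqle (-1.67 ± 0.20), Idi1 (-1.16 ± 0.17), Ebp (-0.65 ± 0.09) and Fdft1 (-0.55 ± 0.07). Its camera adjusted p was 8.61e-07, and adjusted p = 0.468 with an estimated correlation.

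Of 46 cell cycle genes 12 were lower, 1 was higher and 33 did not pass; adjusted over the list alone, 12 were lower and 1 higher. Cyclin E1, Ccne1, fell by 1.00 ± 0.13 and the thymidylate synthase Tyms by 0.91 ± 0.16, while the replication licensing factor Cdt1 was 0.42 ± 0.10 higher. The list medians of the miR-30e arrays were 0.069, -0.43 and -0.28 for replicates 1, 2 and 3, against 0.037 to 0.064 in the controls. The camera adjusted p was 0.000206, adjusted p = 0.982 with an estimated correlation, and 0.0796 without miR-30e replicate 2, where the list mean went from -0.28 to -0.16. Without miR-30e replicate 1 the mean was -0.46 (adjusted p = 6.16e-15), and the fry adjusted p with all arrays was 0.292. Cdt1 lost its call without control replicate 1 or 2 (adjusted p = 0.0599 and 0.0533).

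Of the osteogenic genes, 5 of 24 fell and 1 rose, both over all genes and adjusted over the list alone. The bone genes Runx2 and Spp1 were not among the 24 measured, so nothing is known of them here. The calcification inhibitor Mgp fell by 2.72 ± 0.21, the phosphatase Alpl, which mineralizing cells need, by 1.02 ± 0.10 (adjusted p = 0.000102), and the homeobox gene Msx1 by 0.70 ± 0.08; the stress-regulated factor Atf4 rose by 0.47 ± 0.06. The list did not pass camera (adjusted p = 0.212), but did without miR-30e replicate 1 (adjusted p = 0.0462). Chondrogenic genes were mostly not past the threshold, with 1 of 20 higher, the cartilage regulator Sox9 (0.71 ± 0.22), and 2 lower, including the lubricant gene Prg4 (-0.74 ± 0.11); adjusted over the list alone, 0 rose and 2 fell. Sox9 lost its call without any array but miR-30e replicate 1 (adjusted p up to 0.151) and after quantile normalization (adjusted p = 0.0794). Among adipogenic genes 4 of 28 rose and 8 fell (4 and 9 adjusted over the list alone), with the lipase Lpl at 1.18 ± 0.10 and the fatty acid carrier Fabp4 at -1.07 ± 0.07. Pparg, the main adipogenic regulator, did not pass (-0.20 ± 0.08, adjusted p = 0.101), and camera did not call the list (adjusted p = 0.287), while fry called it lower (adjusted p = 0.0212).

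Matrix genes moved both ways. Of 38 extracellular matrix genes 8 rose and 11 fell (9 and 11 adjusted over the list alone), with Col3a1 and the elastic fibre gene Fbln5 (1.28 ± 0.09) higher and the thrombospondin Thbs1 (-1.95 ± 0.15) and Ltbp2 (-1.37 ± 0.10) lower. Of 23 matrix proteases and inhibitors 6 rose and 6 fell, also over the list alone: Ctsk rose, while Mmp3 (-3.55 ± 0.14), Mmp13 (-2.18 ± 0.09) and the inhibitor Timp1 (-1.44 ± 0.11) fell. Neither list passed camera (adjusted p = 0.902 and 0.940); without miR-30e replicate 1 the extracellular matrix list did (adjusted p = 0.0462), with its mean going from -0.12 to -0.25. The mean was -0.043 without miR-30e replicate 3 and -0.083 without replicate 2, and in both the direction in camera turned to higher.

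Genes previously reported as miR-30 targets did not move in a single direction as a group, though a larger share of them changed than the 21.5% of all genes. Of 45 measured, 14 rose, 10 fell and 21 did not pass (15 and 12 adjusted over the list alone), with a median of 0.067, a mean of -0.087 and a camera adjusted p of 0.940. Runx2, a fixed member, was not among the 45 measured. Igf2 was the member that fell most and accounts for nearly all of the negative mean. As the gene the study took up, it is not independent evidence of the list's direction. The signalling suppressor Socs3 fell by 1.18 ± 0.08, the transcription factor Snai1 by 0.97 ± 0.10 and the BMP mediator Smad1 by 0.68 ± 0.07. Twf1, an actin regulator, was 0.19 ± 0.07 higher and did not pass (adjusted p = 0.106); of its probe sets 1 passed when tested singly (0.26 ± 0.08, adjusted p = 0.0403). Nfyc, the host gene of miR-30e, differed by -0.24 ± 0.08 (adjusted p = 0.0627) and passed without control replicate 3 or without miR-30e replicate 1 (adjusted p = 0.0334 and 0.0413). The Mir30e probe set, named outside the rule, differed by 0.11 ± 0.09 (adjusted p = 0.506); an oligo-dT-primed array does not measure the mature microRNA, so this checks nothing about the labels.

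Of 20 adventitial fibroblast markers 2 rose and 4 fell (2 and 5 adjusted over the list alone): the progenitor antigen Cd34 fell by 3.31 ± 0.08, the receptor Pdgfra by 1.07 ± 0.11 and Fbln1 by 0.76 ± 0.07, while Cd248 rose by 0.83 ± 0.10. This list had a camera adjusted p of 0.164, or 0.0214 with the small nucleolar RNA covariate, and fry called it lower on balance (adjusted p = 0.0200). Markers of modulated smooth muscle cells had 6 higher and 8 lower of 23, also over the list alone, with nestin, Nes, at 1.34 ± 0.07 and Mmp3 lower (camera adjusted p = 0.320, and 0.0462 without miR-30e replicate 1). Of 22 endothelial markers 2 rose, Ptprb (1.06 ± 0.12) and Flt1 (0.53 ± 0.08), and 1 fell, Egfl7 (-0.22 ± 0.07), whose call was lost without any single array (adjusted p = 0.0529 to 0.130); adjusted over the list alone, 2 rose and 0 fell. Of 12 nerve and glial markers 1 fell, Mbp (-0.47 ± 0.07), also over the list alone. Camera called neither of these lists (adjusted p = 0.940 and 0.864).

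The remaining lists did not pass camera with all 6 arrays either. Among 30 unfolded protein response genes 9 rose and 4 fell (9 and 6 adjusted over the list alone), led by the stress-induced Trib3 (1.95 ± 0.15) and Herpud1 (1.22 ± 0.07), with the ubiquitin ligase Syvn1 lower (-0.82 ± 0.07; camera adjusted p = 0.381, and 0.0320 without miR-30e replicate 2). Of 22 p53 targets 3 rose and 4 fell (6 and 5 adjusted over the list alone), with Perp higher and the death receptor Fas lower (-1.74 ± 0.12; camera adjusted p = 0.902). Of 32 autophagy genes 8 rose and 5 fell (11 and 10 adjusted over the list alone), with the cargo receptor Sqstm1 at 0.76 ± 0.09 and the initiating kinase Ulk1 at -0.72 ± 0.07 (camera adjusted p = 0.916). Of 23 small RNA machinery genes 1 rose and 0 adjusted over the list alone. This was Cnot1 (0.27 ± 0.07), whose call was lost without any of 4 single arrays (adjusted p up to 0.0802; list camera adjusted p = 0.421).

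Of the 25 lists, camera at the preset correlation called 7, 1 higher and 6 lower, and 0 held with an estimated correlation, while fry called 9. The median, mean and test differed in sign in 7 lists: reported miR-30 targets, matrix proteases, Notch signalling, interferon response, p53 targets, endothelial markers and leukocyte markers.

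**Figure D3:**
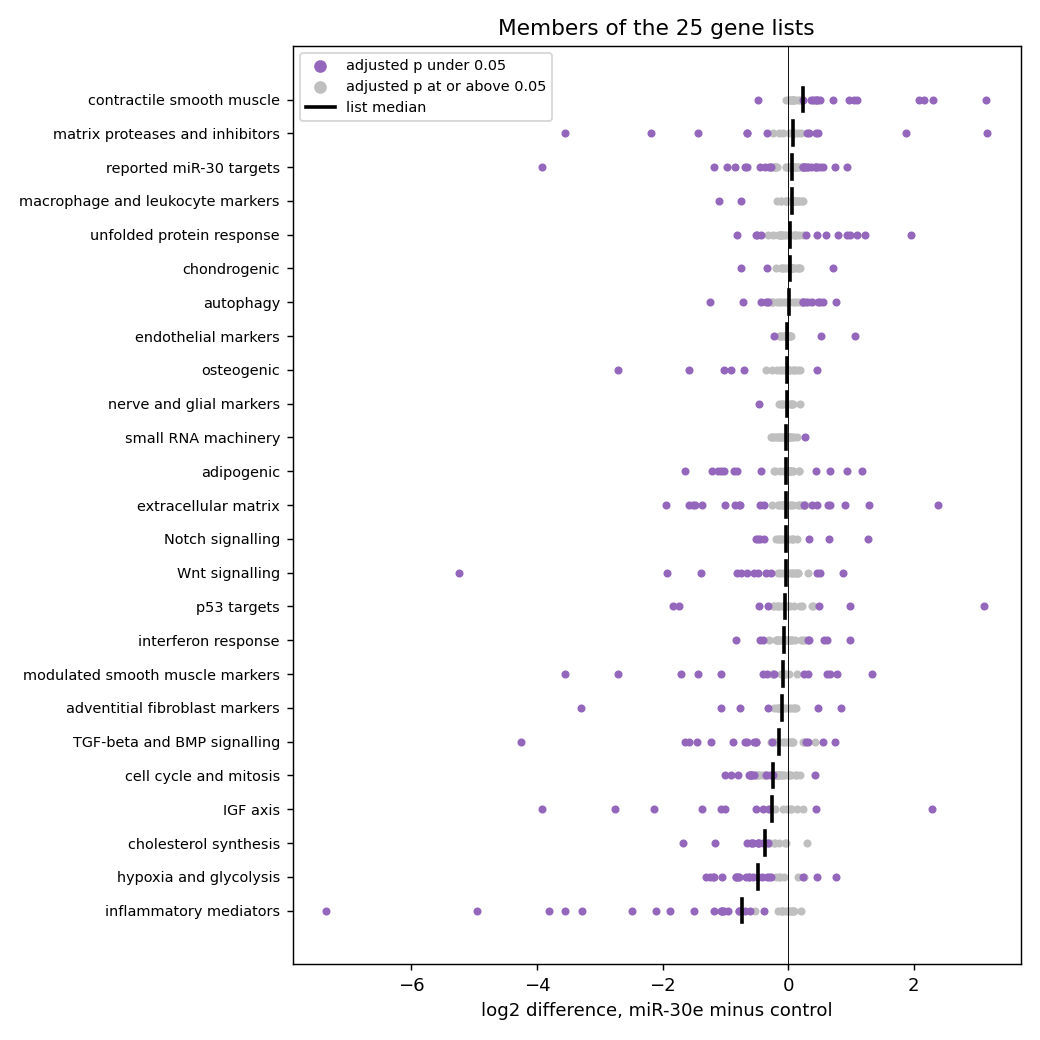
Log2 difference (miR-30e minus control, x axis) of each measured member of the 25 gene lists (rows), purple where the limma adjusted p was under 0.05 and grey otherwise, with a black bar at the list median. The medians run from -0.73 for inflammatory mediators to 0.24 for contractile smooth muscle.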

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

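The counts given here were read after the main comparison had been seen, and no test was planned for them. Of 5430 probe sets not listed in the annotation, 214 were higher in miR-30e cells and 228 lower, with the largest rise at 4.46 and the largest fall at -5.53; 8.14% changed, against 19.7% of probe sets with 1 gene symbol. Of 1605 probe sets with several gene symbols, 150 were higher and 98 lower. No explanation was tested for either set.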

How the results depend on the processing

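Alternatives chosen only after the result was seen were the robust variance model, protein-coding genes, genes with 1 probe set, quantile normalization of gene means, the small nucleolar RNA covariate, leaving out 2 miR-30e arrays together, and the miR-30 target and IGF axis lists without Igf2. The count of 4282 changed genes lay between 3174 and 4357 in 14 alternatives, within 1.5 times the main value. Leaving out each array in turn gave 3174 to 4231 changed genes, 1423 to 1913 higher and 1685 to 2318 lower, and 7 to 10 lists. The cell cycle list lost its call without miR-30e replicate 2. Lists that gained a call were Wnt (without control replicate 1 or miR-30e replicate 2), unfolded protein response (without miR-30e replicate 2), and osteogenic, extracellular matrix and modulated smooth muscle (without miR-30e replicate 1). Without miR-30e replicates 1 and 3 there were 3312 changed genes, of which 2761 were shared with the main call in direction; this leaves 1 miR-30e array, assumed to vary like the controls, and is not among those 14. Acta2, Cdt1, Trpv4, Egfl7, Notch3 and Cnot1 lost their calls there (adjusted p = 0.0534 to 0.278). The counts moved further in these settings. With the small nucleolar RNA median as a covariate there were 2539 changed genes, 1142 higher and 1397 lower. Of them, 2410 were shared with the main call. The covariate takes up part of the group difference and also a residual degree of freedom. How much of the lower count came from each was not tested. In that fit the Wnt and fibroblast lists also passed camera, both at adjusted p = 0.0214, so that 9 lists did, and of the named genes Acta2, Mcm5, Sox9, Egfl7 and Cnot1 lost their calls (adjusted p = 0.0579 to 0.176). A 2-fold threshold left 442, 161 higher and 281 lower, by its construction. Camera with an estimated correlation called 0 of 25 lists where the preset called 7, and fry called 9, adding the Wnt, adipogenic and fibroblast lists and losing the cell cycle list. The estimate was 0.66 for cell cycle genes and 0.24 for contractile genes, against the preset 0.01.

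No pairing by replicate number was visible: same-numbered arrays' deviations correlated at -0.03, -0.30 and -0.12. The values cannot show that the cultures were unpaired. With the replicate block 3390 genes changed, 1521 higher and 1869 lower, and 7 lists passed; of the named genes, Egfl7 (adjusted p = 0.113), Cnot1 (0.0686) and Trpv4 (0.05001) no longer did.

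Of 109 named genes, 96 passed, and 90 of those kept their call without each array in turn; the 6 others were Acta2, Cdt1, Trpv4, Sox9, Egfl7 and Cnot1. Quantile normalization moved the fold of 4 called genes by over 1.5 times, Ctsk, Actg2 and Krt19 to larger rises and Saa3 to a smaller fall, so the order of the largest changes depends on it. Quantile normalization of gene means moved all 20 of the largest changes, and Il33 and Mmp3, by as much, with larger rises (Ctsk 4.56) and smaller falls (Cxcl5 -3.76). Leaving out 1 array did so for Cxcl5 alone (-5.68 without miR-30e replicate 1, and -5.55 without replicates 1 and 3), and testing probe sets singly for Socs3 (-1.80 against -1.18). The direction of a named gene called on either side changed in 0 cases, and sign changes of uncalled values were not counted. The filters on dim probe sets, the pseudocount, the intensity trend and the seed-match test were not run. Signal over background is unknown, so a small difference in a dim gene cannot be told from none.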

Other observations

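All lists and tests in this part were chosen after the result was seen, except the division of the arrays for the list count, and the lists that were fixed in advance. Genes named here that the report does not name were also chosen after their values were seen, and camera p-values of the lists made afterwards were adjusted over those 6 lists alone. Since these lists were picked with the changed genes in view, their p-values are descriptive and not independent tests. Genes induced by the factor ATF4 when amino acids run short rose: 30 of 37 measured genes were higher, 1 was lower and 6 did not pass. They included the asparagine synthetase Asns (0.99 ± 0.09, SE, n = 3 per group), the amino acid transporter Slc7a5 (1.68 ± 0.19), the cystathionine lyase Cth (1.93 ± 0.18) and the tRNA synthetase Wars (1.29 ± 0.13). The list median was -0.35 to -0.38 in the control arrays and 0.50, 0.29 and 0.52 in miR-30e replicates 1, 2 and 3; 7 of its members stand in another list. Its limma camera adjusted p was 1.73e-21, and adjusted p = 0.155 with an estimated correlation.

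Acute-phase and complement genes fell, 17 of 20 with 0 higher, and 5 of them stand in another list. Ceruloplasmin, Cp, fell by 2.77 ± 0.10, the protease inhibitor Serpina3n by 1.94 ± 0.15 and the regulators Cebpd and Cebpb by 1.64 ± 0.16 and 1.11 ± 0.10; the camera adjusted p was 4.02e-20, and adjusted p = 0.0938 with an estimated correlation. NRF2 response genes went both ways, 6 of 22 higher and 4 lower. Of 29 imprinted genes 2 were higher and 5 lower, Igf2 among them. Of 17 excitability and calcium channel genes 1 was higher and 5 lower, among them Cacna1c, the L-type calcium channel of smooth muscle (-2.76 ± 0.11), while the contractile genes rose. None of these 3 lists passed camera (adjusted p = 0.293, 0.0913 and 0.0876), while fry called the imprinted and the excitability lists lower (adjusted p = 0.0237 and 0.00194) but not the NRF2 list (adjusted p = 0.882).

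The first pattern weighed is the rise of contractile with the fall of inflammatory genes. Fewer adventitial fibroblasts in the miR-30e cultures would lower their markers alike. Of 20 markers 2 rose past the threshold, Cd248 (0.83 ± 0.10) and Opcml (0.48 ± 0.09), and 4 fell. Over all genes 1918 of 19935 rose and 2364 fell, so 2 risen markers of 20 are near the share of all genes and cannot decide. Cd34 fell by 3.31 and fry called the list lower (adjusted p = 0.0200), so a loss of fibroblasts or a change in their kind stays open. Leukocytes in the control cultures would put their markers near the inflammatory median of -0.73, but their median was 0.061 with an SD over markers of 0.30. Detection is unknown here, and undetected markers would show little difference whatever the share of leukocytes, so the median cannot decide. Of 25 markers 23 did not pass, and the 2 that did, Cd14 (-1.10) and Cd68 (-0.76), fell. Over all genes 2364 of 19935 fell, so 2 fallen markers of 25 are not above the share of all genes and cannot decide either. Fewer leukocytes, such as macrophages, in the miR-30e cultures stay open. A single array as the source is argued against by the list means, which stayed at 0.51 to 0.65 and -1.34 to -1.12 with 1 array left out, at least 87.3% of their value; with an estimated correlation neither list passed camera (adjusted p = 0.468 for each). An effect of miR-30e may underlie the pattern, as a hypothesis, while any other difference between the transduced cultures stays open and untested.

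The next pattern is the rise of the amino acid response. General endoplasmic reticulum stress would raise the chaperones, but their median was -0.13, with 0 of 12 higher and 3 lower (Pdia4, Calr and Sdf2l1), and all 12 stand in a fixed list (camera adjusted p = 0.0471, adjusted p = 0.372 with an estimated correlation, and 0.0580 in fry). The fixed unfolded protein response list had 9 of 30 higher and 4 lower, and of its 14 members in neither the amino acid nor the chaperone list 5 rose, Herpud1 among them, and 1 fell. These go in opposite directions, so stress of this kind stays open. A difference in medium or density at harvest could also raise these genes and was not tested.

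The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. For changed genes, 1 division, the real one, called 4282, and the highest of the others was 0. For lists, 4 of the 10 called at least as many as the real 7, and the highest other was 10. Each of the other divisions set 2 arrays of a group with 1 of the other, so the group difference stood in both their contrast and their residual, and they give no value for the case of no change.

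The 24 Snord116 probe sets had medians of -0.083, -0.40 and -0.27 in control replicates 1, 2 and 3, and of 2.24, 0.083 and 2.44 in the miR-30e replicates, and 0 passed (smallest limma adjusted p = 0.0592). The small nucleolar RNA covariate did not follow this, at -0.16, -0.24 and 0.026 in miR-30e replicates 1, 2 and 3. Its fit is therefore no adjustment for this difference between arrays, whose cause was not tested. The 20 probe sets outside the annotation with the largest spread within groups had medians of -0.063, -0.47 and -1.29 in the controls and 1.44, -0.17 and 1.69 in miR-30e replicates 1, 2 and 3, and 9 of them passed (smallest adjusted p = 0.00909).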
